A study of Arabidopsis thaliana with 22 samples.

How the data were processed

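Chromatin immunoprecipitation with sequencing (ChIP-seq) measured 2 histone marks in Arabidopsis thaliana, accession Landsberg erecta. H3K4me3 is a mark found over the start of active genes, and H3K27me3 is the mark of Polycomb-repressed genes. Per the labels, the 4 stages were rosette leaves of flowering wild-type plants (leaf), untreated inflorescence apices of ap1 cal plants carrying 35S::AP1:GR (apex t0), the same apices 2 days after 10 µM dexamethasone (apex t2), and wild-type inflorescences from which flowers older than stage 12 had been removed (inflorescence). The ap1 cal double mutant forms cauliflower-like masses of inflorescence meristems, and dexamethasone moves the AP1-glucocorticoid receptor fusion into the nucleus, which starts flower formation in these meristems. There were 2 biological replicates per stage and mark, 16 ChIP libraries in all. The 6 input samples had no file of their own and were not used here.

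The deposited tables list islands, one table per library, each with position, ChIP reads, control reads, p-value, fold over control and adjusted p. Per the submitters' processing notes, CASAVA 1.8.2, BWA 0.6.2-r126, SAMtools 0.1.19, Picard 1.93, bedtools 2.17.0-97 and SICER 1.1 were named, with the TAIR10 genome build. SICER joins neighbouring windows enriched over a control into broad islands. The window size, gap and threshold settings were not given in the sources used here. In the files all 185427 islands started at a multiple of 200 bp, the smallest gap between islands was 600 bp, and the adjusted p of every island lay under 1e-04. The fold of an island is the authors' own value and was used here only within a library, to filter islands or to place one among the rest. Islands were called per library, not on pooled replicates. A gene without an island is a gene below the authors' island threshold, which is not the same as a gene without reads. Per the labels' protocols the 2 replicates differed in sonication time, antibody lot, library kit and sequencer, and replicate 2 pooled technical ChIP reactions. Cauliflower apices gave 15 µg and wild-type tissue 10 µg of chromatin per reaction. The control count was identical on every island of the same bounds in 8 pairs of libraries, the leaf and inflorescence libraries of one replicate and mark and the 2 apex libraries of one replicate and mark, so these pairs shared a control (at least 659 islands compared per pair). The control of leaf and inflorescence therefore differed from that of the apices.

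Depth was read from the islands, since the total reads of the libraries are not in the tables. Island reads ranged from 6635471 to 23673881 for H3K4me3 and from 3779918 to 19379225 for H3K27me3. Replicate 1 was the shallower in each stage and mark, with 3779918 to 14763262 island reads against 13745836 to 23673881 for replicate 2. A deeper library yields islands at lower enrichment, so presence and absence of an island partly follow depth.

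Islands were placed on 27444 protein-coding genes of the 5 nuclear chromosomes from a RefSeq gene table of assembly TAIR10.1. That table differs in name from the authors' build, so it was checked on the data. In 106 of 106 bins of 1 Mb, the overlap of H3K4me3 islands with genes was largest with no offset between the coordinates. No gene coordinate is printed, and island positions are those of the deposited tables, 1-based, on TAIR10. Symbols of their own were found for 10377 genes, and 186 of 186 members of the gene lists matched a locus. A gene was marked in a library when islands covered at least 200 bp of its body. The value of a gene was the sum over islands of ChIP reads times the share of the island inside the gene body, as RPM (reads per 1000000 island reads on tested genes) after trimmed-mean scaling between libraries (TMM, 30% trimmed of log ratios and 5% of mean levels, written for this work), on the scale log2(value + 1).

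Genes marked in both replicates of at least 1 stage were tested, 17631 for H3K4me3 and 8678 for H3K27me3. The planned test was not used: the design named edgeR on reads per gene, but the automatic unit check of the tables reads them as comma-separated, could not register their read columns as counts, and so no count model was run, neither edgeR nor DESeq2. In place of it limma 3.58.1 (R 4.3.3, with statmod 1.5.0) was fitted to the log2 values of the 8 libraries of a mark, with stage as the only term, a mean trend and robust moderation, which leaves 4 residual degrees of freedom. An adjusted p is limma's p after Benjamini-Hochberg adjustment over the genes tested in one mark and comparison, two-sided, with a threshold of 0.05. A fold change is on the log2(RPM + 1) scale with its standard error, and is given only where both stages had islands in all 4 libraries; otherwise island presence and RPM per library are given, since a missing island is no measured zero. A sum over islands called separately in each library moves with how much was called, so the mean percentage of the gene body under islands is given for most of the largest folds. With 2 replicates per stage, p-values measure the spread between these samples, pooled over all 4 stages of a mark. A gene thus has the same standard error in every comparison. A missing island enters the fit as 0 RPM, so a stage without islands in both libraries adds no spread.

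Per the labels' protocols the replicate number is a batch, so the numbers pair the samples. The data showed the same. The differences between replicate 2 and replicate 1 correlated across genes between every pair of stages, with r from 0.429 to 0.614 for H3K4me3 (14688 genes) and from 0.335 to 0.653 for H3K27me3 (5914 genes), above 0.1 in 6 of 6 pairs of each mark. The fit without the block was fixed as the one reported. The fit with the replicate number as a block is given where it changed the call of a named gene or list. It is also given where it moved a count by over 1.5 times, and the calls kept with it are counted below. Counts of genes that gained or lost an island rest on no test. A gained gene was marked in both libraries of one stage and in neither of the other, and beside the count stands the same count for the other pairings of the 4 libraries. A library left out takes away a condition, so this count and that of genes with both marks can then only stay or rise.

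The 11 gene lists, fixed from textbook knowledge, were floral organ identity, meristem and inflorescence, floral organ growth and patterning, anther and pollen wall, flowering time, cell division, photosynthesis, Polycomb and trithorax, housekeeping, root, and seed and embryo. The lists for photosynthesis, root, seed, and anther serve as markers of tissues that a sample might hold. Lists with at least 3 tested members were compared with all other genes by limma's camera, two-sided, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a mark and comparison. Only members marked in some stage were tested, so shares of tested members depend on the mark itself. A member without islands in one stage cannot be lower in the other, which partly fixes the sign of a list. Genes named in the text follow a rule fixed in advance: the 6 largest changes in each direction past the threshold with islands in all 4 libraries, up to 10 list members past the threshold, the 5 gained and 5 lost genes of highest read density, and 12 genes examined in every comparison (AP1, CAL, LFY, AP3, PI, AG, SEP3, STM, WUS, FLC, SOC1 and TFL1). The largest changes and the gained and lost genes were ranked only among genes with a symbol of their own. The text gives a part of these genes, and 1 result is not reported here. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

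Fisher's exact test across genes and permutations of genes (100000) served as descriptions, since genes are not independent replicates. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fit was tested on simulated data for apex t2 against apex t0. Of simulated 4-fold changes it recovered 84.8% for H3K4me3 (14688 genes) and 75.8% for H3K27me3 (5914 genes), of 2-fold changes 32.8% and 43.3%, and of 1.5-fold changes 4.5% and 7.5%, with 2 and 6 unchanged genes called. Alternatives tried were the block, median-of-ratios scaling, total island reads, other gene filters, other gene windows, stricter islands, merged island regions, a floor for genes without islands, another pseudocount, subtraction of control reads, other rules for coverage, and each library left out in turn. The floor gave a gene without an island the lowest island density of the library over its whole body. A marked gene counts only reads inside its islands, so the floor can turn a sign through unequal lengths alone.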

Results

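Trimethylation of histone H3 at lysine 4 (H3K4me3) and at lysine 27 (H3K27me3) was mapped by ChIP-seq in 4 stages of Arabidopsis, with 2 biological replicates each. The stages were rosette leaf, the untreated cauliflower apex (apex t0), the same apex 2 days after dexamethasone (apex t2) and the wild-type inflorescence. Islands held 6635471 to 23673881 reads per library for H3K4me3 and 3779918 to 19379225 for H3K27me3. The tables held 14589 to 16214 H3K4me3 islands per library, covering 16.278 to 21.016 Mb, and 6345 to 8048 H3K27me3 islands covering 17.506 to 25.649 Mb. H3K4me3 islands lay on 15658 genes in both leaf replicates, 16567 in apex t0, 16618 in apex t2 and 16183 in the inflorescence. H3K27me3 islands lay on 6656, 7907, 7917 and 7167 genes, respectively. Replicates of one stage shared a median of 0.81 of their covered length for H3K4me3 and 0.756 for H3K27me3 (Jaccard index), against 0.788 and 0.688 for libraries of different stages with the same replicate number, and 0.731 and 0.636 for the remaining pairs. For H3K27me3 the inflorescence replicates shared 0.591, less than the median of the remaining pairs, and the leaf replicates 0.679. Levels are RPM for replicate 1 and replicate 2, and log2 fold changes are given with their standard errors (2 libraries per stage). A standard error pools the spread of a gene over all 4 stages of a mark. It is thus not the spread of the 2 stages compared alone.

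AP1, the floral meristem identity gene whose fusion protein was induced, was examined first, because the apex plants carried ap1 mutant alleles and an AP1-GR transgene. No H3K4me3 island overlapped AP1 in either leaf library. In apex t2 replicate 1 an H3K4me3 island covered chromosome 1 from 25982401 to 25986400, and in both inflorescence libraries an island ran from 25983601 to 25986400 (TAIR10). H3K27me3 islands lay over AP1 in 8 of 8 libraries, from 25979201 to 25988400 in inflorescence replicate 2 and as 2 short islands in inflorescence replicate 1. Control reads in the H3K4me3 islands over AP1 were 236.1 to 248.2 per kb in the 4 apex libraries, which was 0.808 to 0.90 of the median island of the same library, and the inflorescence libraries, from plants without the transgene, had 0.702 and 0.802 of it. Reads over AP1 in the apex libraries may come from the mutant locus or from the transgene, which were not told apart. This limit holds for every AP1 value from an apex. CAL, the paralogue of AP1 that is also mutated in these apices, carried more H3K4me3 at t0 (21 and 46.2 RPM) than in leaf (0 and 0.476; adjusted p = 0.0145, and past the threshold neither without leaf replicate 1 nor without apex t0 replicate 2), while in the inflorescence islands touched only 7 bp of its body (0.633 and 0.496 RPM).

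**Figure D1:**
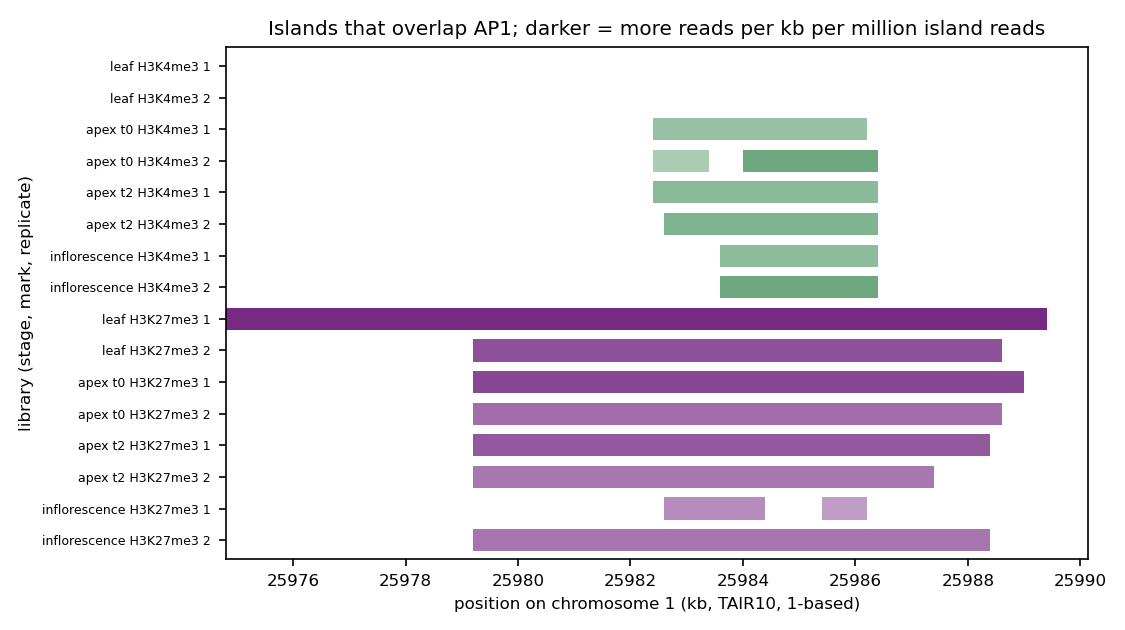
Islands of each library over AP1 (x axis, position on chromosome 1 in kb, TAIR10; y axis, one line per library, H3K4me3 in green and H3K27me3 in purple; darker bars hold more reads per kb for the depth of the library). Both leaf H3K4me3 lines are empty, the 6 other H3K4me3 libraries carry an island that ends at 25986200 or 25986400, apex t0 replicate 2 also has one from 25982401 to 25983400, and H3K27me3 islands lie over the gene in 8 of 8 libraries.

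The comparison of apex t0 with leaf asks how both marks differ between a proliferating meristem and a differentiated organ. Of 22 meristem and inflorescence genes, 19 were tested, which required H3K4me3 in both replicates of at least 1 stage. H3K4me3 lay on all 19 in both apex t0 libraries, and on 7 of them in both leaf libraries. STM (77.8 and 106 RPM), KNAT1 (85.4 and 99), KNAT2 (105 and 105) and KNAT6 (83.1 and 94.3), KNOX homeobox genes that maintain the meristem, carried it in both apex libraries and had no island in leaf. The AP2-domain genes ANT (102 and 124) and AIL6 (60.9 and 97.4), the boundary gene CUC2 (41.9 and 53.6) and the cell-cycle kinase gene CDKB1;1 (42 and 63) did the same, with adjusted p from 0.000404 (ANT) to 0.00615 (CUC2). These p-values count the missing leaf islands as 0 RPM in both libraries, so leaf added no spread to them. RBCS1B, a Rubisco small subunit gene, fell from 177 and 128 RPM in leaf to 23.7 and 29.1 in the apex (log2 fold change -2.47 ± 0.21, adjusted p = 0.00406), with 42% of its body under islands against 98% in leaf. In all 1418 genes passed the threshold, 670 higher and 748 lower in the apex. Each moved the same way in both replicates, which a call with 2 libraries per stage all but requires.

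Of genes with H3K4me3 islands in all 4 libraries, AGG3, a G-protein gamma subunit gene, rose by 2.69 ± 0.34 on the log2 scale, the xyloglucan-modifying XTH9 by 2.55 ± 0.17 and the endoglucanase GH9B1 by 2.39 ± 0.25. The tonoplast dicarboxylate transporter TDT had the deepest fall among those with a symbol of their own, -3.40 ± 0.41, and BLH4 and BLH2, BEL1-like homeobox genes of leaf-margin growth, changed by -2.82 ± 0.27 and -2.71 ± 0.43. The peroxisomal malate dehydrogenase gene PMDH2 changed by -2.57 ± 0.28. These folds include the covered share of the gene body, which went from 17% in leaf to 70% in the apex for AGG3, 49% to 90% for XTH9 and 17% to 43% for GH9B1, and from 59% to 13% for TDT, 41% to 20% for BLH4, 39% to 20% for BLH2 and 88% to 29% for PMDH2. Among the 5 densest gained genes with a symbol of their own were the growth-regulating factors GRF5 (locus AT3G13960, 127 and 138 RPM) and GRF6 (locus AT2G06200, 79 and 77.6), and among the lost ones the bHLH gene HBI1 (216 and 86.9 in leaf) and NAC6 (104 and 92.7). The calls of AGG3, BLH2, TDT and HBI1 ended without leaf replicate 1, those of AGG3 and BLH2 also without apex t0 replicate 2, and that of BLH2 also without apex t0 replicate 1. RAV2, a repressor of flowering, had H3K4me3 in leaf (178 and 101) and no island in the apex, with adjusted p = 0.0603, and 0.0405 with the replicate block. Of 9 fixed gene lists tested, 3 passed. List medians count a gene without an island as 0 RPM and are no measured folds where islands were gained or lost. Members without a leaf island could not be lower in the apex, so shared signs are partly fixed by which genes were tested. Of 14 tested cell division genes 4 rose and 0 fell (12 rose adjusted over the list alone; median log2 fold change 3.85), and of 19 meristem and inflorescence genes 9 rose and 0 fell (10 over the list alone; median 3.96), each with adjusted p = 3.11e-08, and adjusted p = 0.262 with an estimated correlation. Of the 4 cell division genes 2 are ANT and AIL6, organ growth and meristem regulators. Of 24 photosynthesis genes 0 rose and 6 fell (8 over the list alone; median -0.65, adjusted p = 1.26e-07), and adjusted p = 0.262 with an estimated correlation. The other lists had adjusted p between 0.0728, for floral organ identity with AP1 as the only member that rose, and 0.951, for the anther list. Apex reads on AP1 may include the transgene. The root list had 1 tested gene and the seed and embryo list 0 for H3K4me3. In all 23 list results past the threshold, of 76, the median, the mean and the test had the same sign, and in 16 of those not past it they did not.

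H3K27me3 fell on KNAT6, AIL6 and ANT among these regulators, while STM did not pass (-0.83 ± 0.24, adjusted p = 0.121). KNAT6 fell from 739 and 621 RPM in leaf to 39.8 and 35.5 in the apex (log2 fold change of island reads -4.13 ± 0.32, adjusted p = 0.0016), and islands covered 19% of its body in the apex against 100% in leaf. LFY, the floral meristem identity regulator, changed by -1.78 ± 0.26 (adjusted p = 0.0113), AGL6 by -1.62 ± 0.17, AIL7 by -2.46 ± 0.27 and AIL6 by -1.33 ± 0.17, with the covered share going from 100% in leaf to 60% for LFY, 100% to 83% for AGL6, 81% to 25% for AIL7 and 51% to 37% for AIL6. Islands present in both leaf libraries were absent from both apex libraries on BLH9, the meristem gene PENNYWISE (471 and 470 RPM in leaf), ANT (202 and 237), the flowering activator SOC1 (422 and 112), FUL (738 and 423) and CYCD3;1 (81.8 and 55.4). SVP (233 and 256), RAV2 (253 and 215) and TEM1 (97.4 and 79.4), each a repressor of flowering, had islands in the apex and none in leaf, as did the chlorophyll-binding protein gene CAB2 (42.2 and 42.2). The flowering time list as a whole did not pass (1 of 10 genes higher, 2 lower, median -0.27, adjusted p = 0.244). UNE10, a bHLH gene, rose by 3.00 ± 0.26 and the cytosolic fumarase gene FUM2 by 2.79 ± 0.26. LHT1 rose by 2.49 ± 0.50 and KCS20 by 2.26 ± 0.45 (adjusted p = 0.0389 and 0.0384), with adjusted p = 0.0518 and 0.0683 with the replicate block. The covered share went from 16% to 82% for UNE10, 13% to 77% for FUM2, 26% to 63% for LHT1 and 34% to 88% for KCS20. Of these calls those of FUL, LHT1 and KCS20 ended without any 1 of 6 libraries, apex t0 replicates 1 and 2 among them, that of AIL6 without either apex t0 replicate, and that of LFY without leaf replicate 1 or apex t0 replicate 2. Of 13 tested floral organ identity genes all 13 were marked in both leaf libraries and 12 in both apex libraries, and 1, AGL6, was called lower (median -0.10, mean -0.62). AP3 differed by 0.02 ± 0.14, AG by 0.01 ± 0.19, SEP3 by 0.03 ± 0.26 and PI by -0.13 ± 0.24, and the flowering repressor FLC by 0.01 ± 0.24. TFL1 (-0.81 ± 0.22), AP1 (-0.41 ± 0.49), CAL (-0.21 ± 0.16) and WUS (-0.05 ± 0.24) did not pass either. In all 833 genes passed, 482 higher and 351 lower.

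By list, H3K27me3 fell on 6 of 21 tested meristem and inflorescence genes and rose on 1, SVP (11 and 1 over the list alone; median -0.77, adjusted p = 9.26e-05), and adjusted p = 0.0967 with an estimated correlation. It fell on 3 of 4 cell division genes (3 over the list alone; adjusted p = 0.00441), and adjusted p = 0.153 with an estimated correlation. The 3 are CYCD3;1, ANT and AIL6, of which ANT and AIL6 are organ growth and meristem regulators rather than cell-cycle genes. It rose on 1 of 5 photosynthesis genes, CAB2 (2 over the list alone; median 3.39, adjusted p = 0.0395), and adjusted p = 0.4 with an estimated correlation. The remaining lists, among them root (11 genes, 0 past the threshold) and seed and embryo (16 genes, 1 lower), had adjusted p from 0.244 to 0.546.

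Of the calls, 708 for H3K4me3 and 214 for H3K27me3 had islands in all 4 libraries, and there the covered length moved the same way in 97.5% and 87.4%, by a median of 0.58 and 0.51 on the log2 scale against 1.09 and 1.15 for the reads. Another 699 and 613 calls were genes that gained or lost an island, with a missing island counted as 0 RPM. The H3K4me3 count was 2382 with the replicate block, and with single libraries left out it ran from 659 (without apex t0 replicate 1) to 3135 (without leaf replicate 2); 368 of the 1418 genes kept their call with each library left out in turn. For H3K27me3 the count ran from 636 (without apex t0 replicate 1) to 1698 (without leaf replicate 2), and 560 of 833 genes kept their call. By presence of islands alone, 600 genes gained and 463 lost H3K4me3, and 724 gained and 353 lost H3K27me3. The same counts for libraries paired by replicate number, 345 and 359, and for the crossed pairing, 40 and 32, were lower. Without leaf replicate 2 the genes that gained or lost an island rose from 1063 to 2253 for H3K4me3 and from 1077 to 2557 for H3K27me3. Such totals can only stay or rise, but their balance moved with the library left out. Without leaf replicate 1, 670 genes gained and 1109 lost H3K4me3, and 852 gained and 974 lost H3K27me3. Without leaf replicate 2 it was 1619 gained and 634 lost, and 1653 gained and 904 lost.

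**Figure D2:**
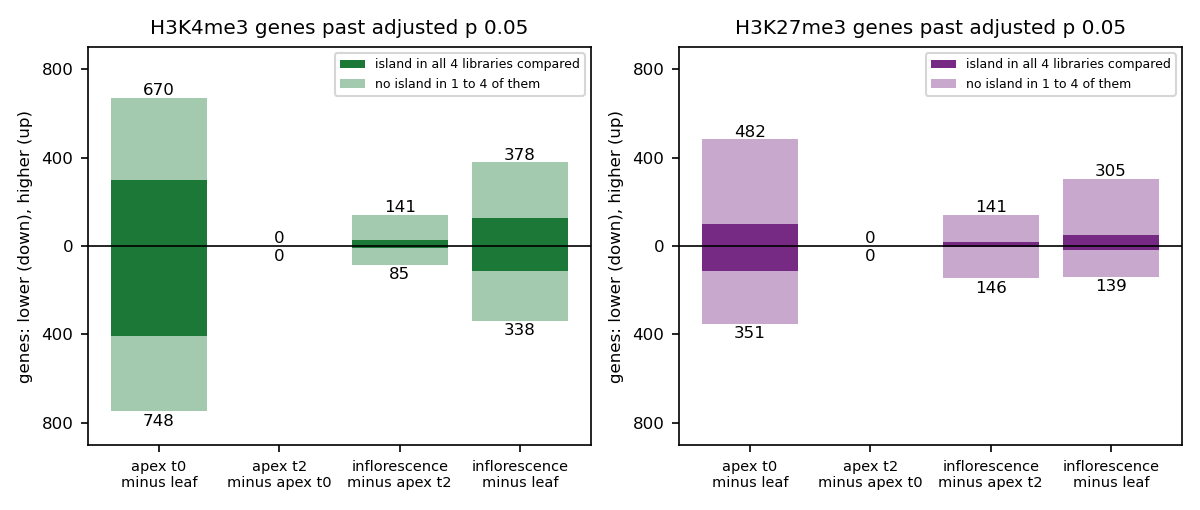
Genes past an adjusted p of 0.05 in each comparison (y axis, number of genes, higher upwards and lower downwards; left H3K4me3, right H3K27me3). Dark parts are genes with islands in all 4 libraries compared, pale parts are genes without an island in some of them; apex t0 against leaf has the tallest bars (1418 and 833 genes), and apex t2 against apex t0 has 0.

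Apex t2 against apex t0 asks what changes in the 2 days after AP1 induction. H3K4me3 islands were gained in both t2 libraries on 2 floral organ identity genes, AP3 and SEP1, without any single gene passing the threshold. AP3, which specifies petals and stamens, had no island at t0 and islands in both t2 libraries (14.5 and 27.8 RPM, at chromosome 3 from 20120401 to 20121200 in both). These islands had folds over control of 1.66 and 2.02, against medians of 4.458 and 3.393 over all islands of the same libraries. AP3 thus had no island of fold 2 or more in replicate 1 of t2. Its partner PI had 0 and 11.6 RPM at t0 and 14.9 and 29.8 at t2, and SEP3 gained an island in replicate 2 of t2 alone (28.5 RPM). SEP1, chosen after its values were seen, had none at t0 and 13.5 and 17.7 RPM at t2. The pollen wall gene LAP6 (22.4 and 23.4 RPM) also had islands at t2 alone, and NGA2, SOFL1, ZFP8 and FAF4 had islands at t0 alone (22 and 28.5 RPM for NGA2). AP1 itself differed by 0.20 ± 0.25, CAL by 0.13 ± 0.74, STM by 0.06 ± 0.48 and SOC1 by -0.11 ± 0.43. These standard errors also hold the spread of leaf and inflorescence. LFY differed by 0.43 ± 2.55, with 86.9 and 73.5 RPM at t0 and 109 and 106 at t2. Its large standard error came from replicate 2 of leaf and of inflorescence, with 0 RPM against 73.5 and 74 in replicate 1. AG had no H3K4me3 island in any of these libraries.

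As a group, the floral organ identity genes were higher in H3K4me3 at t2 at the preset correlation, but not with an estimated one (0.581). Members without an island at t0, such as AP3, SEP1 and SEP3, could not be lower at t2. A shared sign is thus partly fixed by which genes were tested. All 9 tested members had a positive log2 fold change (median 2.44, adjusted p = 1.71e-11), with adjusted p = 0.166 with an estimated correlation, and 8 of them were marked in both t2 libraries against 4 in both t0 libraries. No member passed over all genes, and 2 passed adjusted over the list alone. The anther list, with 4 tested genes, was higher (median 1.19, adjusted p = 3.73e-05), and adjusted p = 0.166 with an estimated correlation. Photosynthesis genes were slightly lower (median -0.04, 18 of 24 negative, adjusted p = 0.0134), and adjusted p = 0.692 with an estimated correlation. The other H3K4me3 lists had adjusted p from 0.265 to 0.761, and none of the 10 lists testable for H3K27me3 passed, with adjusted p from 0.223 to 0.925.

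H3K27me3 lay on 12 of 13 tested floral organ identity genes in both t0 and in both t2 libraries. AP3 differed by -0.19 ± 0.14, PI by -0.02 ± 0.24, AG by -0.05 ± 0.19, SEP3 by -0.23 ± 0.26 and WUS by 0.00 ± 0.24, none past the threshold. LFY had 135 and 90.9 RPM at t0 and 94.9 and 84 at t2. LSH3 had islands at t2 alone (45.9 and 46.2 RPM), and THI1, TRM27 and CNGC3 at t0 alone, with adjusted p from 0.0847 to 0.112. Limma called 0 genes for either mark, with an unadjusted p under 0.05 for 155 H3K4me3 genes (0.88%) and 36 H3K27me3 genes (0.41%), and 0 with the replicate block. Evenly spread p-values would put a share of 0.05 of the genes there, so the test was conservative here. The 0 calls therefore do not show that the marks stayed alike. With islands of fold 2 or more, 22 genes passed for H3K27me3, and 11 passed without inflorescence replicate 1. Islands were gained on 14 and lost on 48 genes for H3K4me3 and gained on 8 and lost on 23 for H3K27me3, fewer than when the same libraries were paired by replicate number (411 and 517), against 34 and 31 for the crossed pairing. Those totals of 62 and 31 became 430 without apex t0 H3K4me3 replicate 1 and 288 without apex t0 H3K27me3 replicate 2. A library left out drops a condition, so such totals can only stay or rise. Without apex t0 H3K4me3 replicate 2, 263 genes gained and 84 lost an island. Without any other of these H3K4me3 libraries losses exceeded gains.

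**Figure D3:**
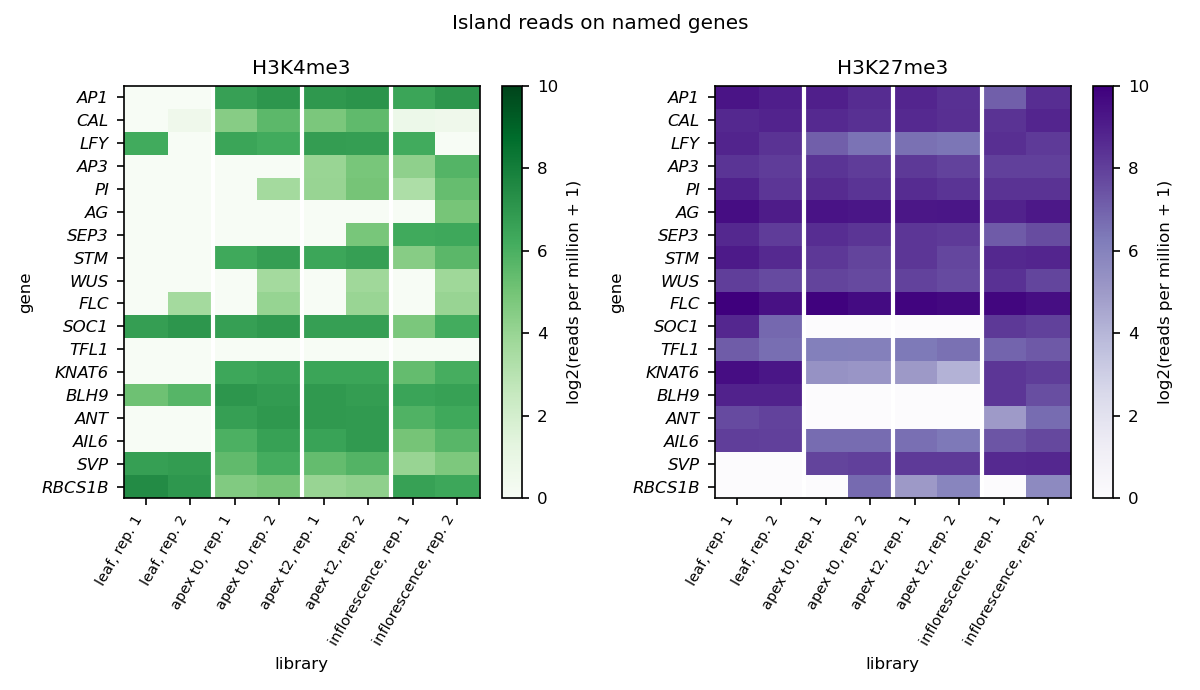
RPM of island reads on 18 genes in each library (y axis, gene; x axis, library by stage and replicate; colour, log2(RPM + 1); left H3K4me3, right H3K27me3; palest, no island). AP3 gains H3K4me3 in both apex t2 libraries, STM, KNAT6 and ANT carry it in the 6 libraries other than leaf, and SOC1, BLH9 and ANT lack H3K27me3 in the 4 apex libraries.

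The inflorescence against apex t2 compares developing wild-type flowers and stem with induced cauliflower apices. Genotype, dexamethasone, chromatin amount and control differed along with tissue here and cannot be told apart. H3K27me3 was higher in the inflorescence on regulators from which it was missing or low in the apex. KNAT6 rose from 31.8 and 16.2 to 307 and 269 RPM (log2 fold change 3.60 ± 0.32, adjusted p = 0.00598), LFY by 1.83 ± 0.26 (adjusted p = 0.0237) and the sucrose transporter gene SUT4 by 1.59 ± 0.23. SOC1 (292 and 248 RPM), BLH9 (309 and 189) and ANT (30.8 and 102) had islands in both inflorescence libraries and none at t2, although for ANT the log2 fold change was -0.33 with genes without an island set to the lowest island density. AIL6 rose by 1.09 ± 0.17 (adjusted p = 0.0346, and 0.0795 with the replicate block). HPL1 changed by -2.28 ± 0.25 and GATA12 by -1.27 ± 0.11, while CAB2 and STOMAGEN, whose peptide promotes stomata, had islands at t2 (36.6 and 39 RPM, 58.2 and 78.6 RPM) and none in the inflorescence. The covered share went from 14% at t2 to 91% for KNAT6, 45% to 85% for LFY, 19% to 46% for SUT4, 35% to 45% for AIL6, 49% to 19% for HPL1 and 80% to 53% for GATA12. STM differed by 0.70 ± 0.24, SEP3 by -0.76 ± 0.26 and AP1 by -0.79 ± 0.49, none past the threshold; of the 12 fixed genes only LFY and SOC1 passed. The 287 genes past the threshold were 141 higher and 146 lower.

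Of 21 tested meristem and inflorescence genes 4 rose in H3K27me3 and 0 fell (5 over the list alone; median 0.70, adjusted p = 1.17e-08), and adjusted p = 0.0309 with an estimated correlation, or 0.0653 with that correlation and the replicate block. Of 5 photosynthesis genes 1 fell, CAB2 (1 over the list alone; median -2.68, adjusted p = 0.0235), and adjusted p = 0.304 with an estimated correlation. Of 4 cell division genes ANT and AIL6 rose (2 over the list alone; adjusted p = 0.0341, and 0.0831 with the replicate block), and adjusted p = 0.304 with an estimated correlation. The other H3K27me3 lists had adjusted p from 0.209 to 0.939.

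H3K4me3 in the same comparison rose on RBCS1B, from 14.9 and 18.1 to 98.7 and 81.9 RPM (2.38 ± 0.21, adjusted p = 0.03), and on the vacuolar calcium exchanger CAX1 (2.16 ± 0.22). LpxC1, LpxC3, LpxC4 and LpxC5, near-identical copies whose reads cannot be assigned with certainty, rose by 1.95 to 2.46. BAS1, a brassinosteroid-inactivating enzyme, changed by -2.30 ± 0.32 (adjusted p = 0.0425). The covered share went from 32% at t2 to 86% for RBCS1B, 31% to 65% for CAX1, 29% to 55% for LpxC4 and 70% to 15% for BAS1. CUC2 (43.3 and 48.2 RPM) and CUC3 (44.2 and 65) had islands at t2 and none in the inflorescence, as did FPF1 and PUP4, and LAP6 did so too (adjusted p = 0.0385, and 0.0615 with the replicate block), with a log2 fold change of 0.34 when genes without an island were set to the lowest island density. SEP3 had H3K4me3 islands in both inflorescence libraries (75.8 and 80 RPM, chromosome 1 from 8594001 to 8596000 in replicate 1) against 0 and 28.5 RPM at t2, with adjusted p = 0.673. STM differed by -1.54 ± 0.48 and SOC1 by -1.22 ± 0.43, and none of the 12 fixed genes passed. In all 226 genes passed, 141 higher and 85 lower, and 128 of them also passed with the replicate block.

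All 19 tested meristem and inflorescence genes had a negative H3K4me3 log2 fold change (median -1.22); 2 fell, CUC2 and CUC3 (3 over the list alone; adjusted p = 5.32e-12), and adjusted p = 0.154 with an estimated correlation. All 24 photosynthesis genes had a positive one (median 0.50); 1 rose, RBCS1B (6 over the list alone; adjusted p = 1.41e-13), and adjusted p = 0.154 with an estimated correlation. The cell division list was lower (median -0.67, 14 of 14 negative, 0 past the threshold, adjusted p = 0.00217), as were floral organ growth (median -0.69, 0 past the threshold, adjusted p = 0.0123) and the anther list (1 of 4 fell, LAP6, 1 over the list alone, adjusted p = 0.048), each with adjusted p = 0.51 with an estimated correlation. Polycomb and trithorax, flowering time, housekeeping and floral organ identity had adjusted p from 0.455 to 0.941.

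Of these calls 33 for H3K4me3 and 23 for H3K27me3 had islands in all 4 libraries, with the covered length moving the same way in 93.9% and 87.0% (median 0.83 and 0.65 against 1.28 and 1.43 for the reads, log2). The calls were fragile: with any 1 of the 8 libraries left out, 0 to 2 genes passed for H3K4me3, and for H3K27me3 the count ran from 0 (without apex t2 replicate 2) to 980 (without inflorescence replicate 2), with 0 of the 226 and 0 of the 287 genes kept throughout. By islands alone, 252 genes gained and 288 lost H3K4me3 and 207 gained and 199 lost H3K27me3, against 194 and 374 for pairing by replicate number and 35 and 47 for the crossed pairing. Without inflorescence replicate 2 the totals of 540 and 406 became 1255 and 1592, and such totals can only stay or rise. With islands of fold 2 or more, 160 genes gained and 410 lost H3K4me3.

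Inflorescence against leaf compares the 2 wild-type tissues. H3K4me3 lay on 8 of 9 tested floral organ identity genes and 11 of 19 meristem and inflorescence genes in both inflorescence libraries, and on 2 and 7 in both leaf libraries. These lists have 14 and 22 members, of which only those marked in some stage were tested. AP1 (87.5 and 131 RPM), SEP1 (33.4 and 46), AP3 (17.8 and 53.3), ANT (57.7 and 78), KNAT2 (38.2 and 62.1) and STM (21.4 and 47.7) had no island in leaf, with adjusted p from 0.000566 (AP1, ANT) to 0.0248 (AP3). Here too the p-values count the missing leaf islands as 0 RPM. With genes without an island set to the lowest island density the sign turned, to -0.99 for KNAT2, -0.72 for STM, -0.18 for SEP1 and -0.10 for AP3. That density filled the whole gene body in leaf, while inflorescence islands covered 19% of it for KNAT2, 34% for STM, 27% for SEP1 and 46% for AP3. The turn partly follows these unequal lengths and does not decide against the gains, which rest on island presence. The calls of STM and SEP1 ended without apex t2 replicate 2, and that of AP3 without any 1 of 6 libraries. SEP3 had islands in both inflorescence libraries and none in leaf but did not pass (adjusted p = 0.114). AG had an H3K4me3 island in inflorescence replicate 2 alone (28.8 RPM). XTH9 rose by 2.49 ± 0.17 and GH9B1 by 2.22 ± 0.25, and SVP changed by -2.39 ± 0.34, UGT76C2 by -2.35 ± 0.29 and RAP2.7, a repressor of flowering, by -1.84 ± 0.28, but the calls of SVP, UGT76C2 and RAP2.7 each ended without leaf replicate 1 and without either apex t2 replicate, and that of GH9B1 without apex t2 replicate 2. The covered share went from 49% in leaf to 90% for XTH9, 17% to 43% for GH9B1, 45% to 12% for SVP, 99% to 28% for UGT76C2 and 81% to 37% for RAP2.7. The pattern of SVP was mirrored in H3K27me3, which it carried in the inflorescence (402 and 427 RPM) and not in leaf. TEM1 and RAV2 (237 and 219 RPM) gained H3K27me3 as well, UNE10 rose by 3.45 ± 0.26 and the nitrate transporter gene NRT1:2 by 2.13 ± 0.10, and JAZ10 changed by -2.02 ± 0.28, GATA12 by -1.82 ± 0.11 and AIL7 by -1.48 ± 0.27. The H3K27me3 covered share went from 16% to 78% for UNE10, 35% to 82% for NRT1:2, 75% to 39% for JAZ10, 100% to 53% for GATA12 and 81% to 30% for AIL7. CYCD3;1 (81.8 and 55.4 RPM in leaf) and AGP11, a pollen arabinogalactan protein gene (75.5 and 70.7), had H3K27me3 in leaf alone. KNAT6 and SOC1, which differed between apex and leaf, are not called here for H3K27me3 (SOC1 0.31 ± 0.79), and AP3 (-0.23 ± 0.14), AG (-0.28 ± 0.19) and WUS (0.30 ± 0.24) did not pass either, nor did any other of the 12 fixed genes. The calls of AIL7 and JAZ10 ended without leaf replicate 2 and leaf replicate 1, respectively, and that of AIL7 also without 5 other libraries.

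By list, 6 of 19 meristem and inflorescence genes rose and 1, SVP, fell in H3K4me3 (6 and 2 over the list alone; median 0.36, adjusted p = 0.0151), and adjusted p = 0.476 with an estimated correlation. Of the 6, KNAT2, STM, KNAT6 and KNAT1 turned to -0.99, -0.72, -0.64 and -0.19 with genes without an island set to the lowest island density, and so did SEP1 (-0.18), AP3 (-0.10) and AIL6 (-0.94) of the lists that follow. Of 9 floral organ identity genes 3 rose, AP1, SEP1 and AP3 (6 over the list alone; median 5.00, adjusted p = 5.24e-06), and of 14 cell division genes 3 rose (ANT, AIL6 and CDKB1;1, of which only CDKB1;1 is a cell-cycle gene; 6 over the list alone; median 3.10, adjusted p = 5.89e-08), each with adjusted p = 0.453 with an estimated correlation. Photosynthesis genes were lower (median -0.15, 0 of 24 past the threshold, adjusted p = 0.0334), and adjusted p = 0.56 with an estimated correlation. In H3K27me3, 13 floral organ identity genes were lower as a group (median -0.46, 0 past the threshold, adjusted p = 0.000654), and adjusted p = 0.609 with an estimated correlation. Cell division genes were lower (1 of 4, CYCD3;1, 1 over the list alone, adjusted p = 0.0158), and adjusted p = 0.437 with an estimated correlation. The other lists had adjusted p from 0.197 to 0.761 for H3K4me3 and from 0.169 to 0.611 for H3K27me3.

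For H3K4me3 716 genes passed (378 higher, 338 lower), 241 of them with islands in all 4 libraries, and for H3K27me3 444 (305 higher, 139 lower), 70 of them with islands in all 4; covered length moved the same way in 97.1% and 95.7% of these (median 0.61 and 0.71 against 1.04 and 1.28 for the reads, log2). The count ran from 68 (without apex t2 replicate 2) to 1835 (without leaf replicate 2) for H3K4me3 and from 387 (without apex t2 replicate 2) to 1286 (without leaf replicate 2) for H3K27me3, and 68 and 366 genes kept their call throughout. Islands were gained and lost on 308 and 308 genes for H3K4me3 and on 282 and 157 for H3K27me3; pairing by replicate number gave 537 and 1073, the latter more than the 439 of the stages, and the crossed pairing gave 42 and 31. The totals of 616 and 439 became 1498 without leaf H3K4me3 replicate 1 and 1454 without leaf H3K27me3 replicate 2, and such totals can only stay or rise. For H3K4me3, 378 genes gained and 1120 lost an island without leaf replicate 1, and 1080 gained and 366 lost one without leaf replicate 2. With islands of fold 2 or more, 169 genes gained and 448 lost H3K4me3.

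Both marks met on the same genes less often than independent lists would give. In leaf 923 genes carried both in both replicates, against 3797.5 expected (odds ratio 0.0661), in apex t0 1643 against 4773.2, in apex t2 1638 against 4793.9 and in the inflorescence 1194 against 4226.2. Islands of the marks overlapped by at least 200 bp on 741, 1381, 1357 and 997 of these genes. With at least 0.5 of the body covered the counts were 282, 569, 523 and 392, and with islands of fold 2 or more 643, 1046, 903 and 594. The leaf count became 1699 without leaf H3K4me3 replicate 1, and with a library left out it can only stay or rise. The tissues hold several cell types, so both marks on a gene need not come from one cell.

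Where a gene changed in both marks, the directions were mostly opposite. In apex t0 against leaf, 55 of the 2615 genes tested for both were higher in H3K4me3 and lower in H3K27me3, against 21.64 expected from independent lists (Fisher's exact p = 4.68e-12, adjusted over 16 tests 2.5e-11), among them ANT, AIL6, AIL7, KNAT6 and BLH9, and 93 were lower in H3K4me3 and higher in H3K27me3 against 46.04 (p = 2.5e-13, adjusted 4e-12), among them NHL1 and TDT. Only 5 were higher in both (36.84 expected) and 2 lower in both (27.05 expected). In the inflorescence against leaf the opposite pairs were 21 and 36 (6.86 and 15.69 expected, Fisher's exact p = 2.06e-06 and 7.85e-07, adjusted 4.71e-06 and 2.09e-06), with 0 genes changing alike, and against apex t2 they were 4 and 1 (3.25 and 1.71 expected; Fisher's exact p = 0.565 and 1). With only genes marked in all 16 libraries, opposite changes numbered 9 for apex t0 against leaf, 2 for inflorescence against leaf and 0 for inflorescence against apex t2, against 148, 57 and 5. The sum of opposite changes was 84 for apex t0 against leaf without apex t0 H3K4me3 replicate 1 and 223 without inflorescence H3K27me3 replicate 2, against 148. It was 7 for inflorescence against leaf without apex t2 H3K4me3 replicate 2, against 57, and 19 for inflorescence against apex t2 without inflorescence H3K27me3 replicate 2, against 5. Across genes, which are not independent replicates, the log2 fold changes of both marks correlated with r = -0.422 (Spearman -0.547) for apex t0 against leaf, r = -0.341 (-0.493) for inflorescence against leaf and r = -0.222 (-0.387) for inflorescence against apex t2, each with a permutation p of 1e-05, the smallest the permutations can give (1.23e-05 adjusted over the 16 correlations). For apex t2 against apex t0 r was -0.019 (permutation p = 0.328, adjusted 0.328) and Spearman -0.167 (permutation p = 1e-05, adjusted 1.23e-05). Among the 456 genes with both marks in all 16 libraries, r was -0.556, -0.553, -0.309 and -0.131 in the same order, the last with a permutation p of 0.00579 (adjusted 0.00618) and the others with 1e-05.

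**Figure D4:**
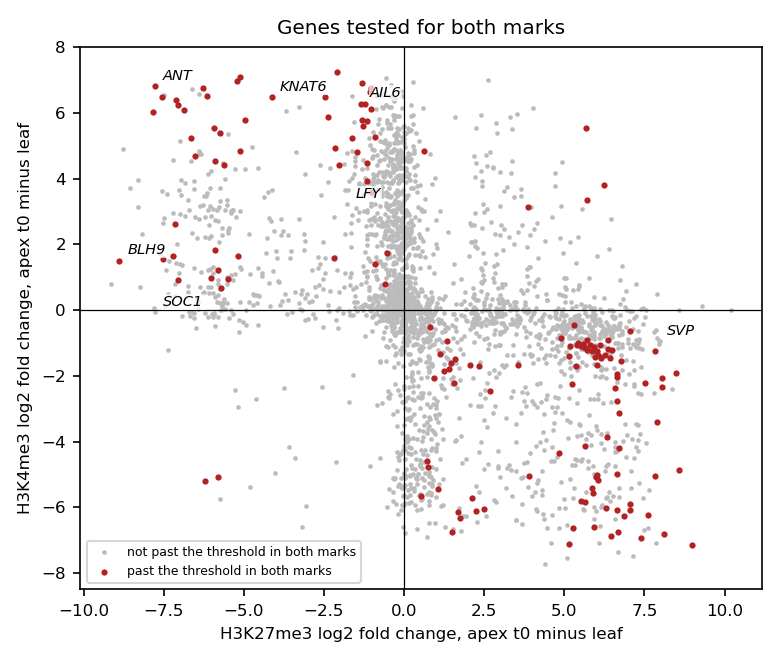
Log2 fold change of H3K27me3 (x axis) and of H3K4me3 (y axis) for apex t0 against leaf, one point for each of the 2615 genes tested for both marks; red points passed the threshold in both. Red points lie mostly in the upper left, with ANT, KNAT6, AIL6 and BLH9, and the lower right, 55 and 93 genes.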

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

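In inflorescence H3K4me3 replicate 2 an island covered the plastid chromosome, 154400 bp, which no comparison used, since genes came from the 5 nuclear chromosomes. It held 288494 ChIP reads and 307386 control reads, fewer in the ChIP, and stood out because the deposited fold, which scales for the ratio of the ChIP to the control library (0.778), was 1.206. It held 1.65% of the island reads of that library, and 1 of 16 libraries had such an island. Reads on tested nuclear genes set the scaling, so it does not enter the RPM values. No technical or biological explanation was tested for it.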

How the results depend on the processing

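Counts were recomputed with 1 choice changed at a time, except for merged island regions. Those took the place of genes and also had to be present in all 8 libraries. Total island reads as scaling, 300 bp added on either side of the gene body, subtraction of control reads, a pseudocount of 5, and leaving out libraries for lists, both marks and opposite changes were chosen after seeing the data. The planned DESeq2 test and the planned window around the gene start were not run, because the read columns could not be registered as counts and the gene table gives no strand. Of the values for counts under the alternatives other than leaving out a library, 104 stayed within 1.5 times and 44 did not. For single genes and lists, 2270 such values kept direction and side of the threshold, 227 lost the call, 15 gained it and 9 changed sign. In each case below the cause was not tested, except that stricter gene sets test fewer genes.

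The replicate block kept 1417 of 1418 H3K4me3 calls for apex t0 against leaf. For inflorescence against apex t2 it kept 128 of 226, and for inflorescence against leaf 709 of 716. In the same order, 795 of 833, 279 of 287 and 414 of 444 H3K27me3 calls were kept. With the replicate block, 2382 genes changed in H3K4me3 for apex t0 against leaf. The block gave RAV2 a call there (adjusted p = 0.0405) and took calls from PAP17 (0.0535), LAP6 (0.0615) and SUMO3 (0.0515) in H3K4me3 for inflorescence against apex t2. In H3K27me3 it took calls from LHT1 (0.0518) and KCS20 (0.0683) for apex t0 against leaf, from AIL6 (0.0795), ABCB16 (0.0573), PnsB3 (0.0701) and the cell division list (0.0831) for inflorescence against apex t2, and from XRCC4 (0.0547), iqd21 (0.0734), HPL1 (0.0554) and FBA4 (0.0845) for inflorescence against leaf. With an estimated correlation it also took the call of the H3K27me3 meristem and inflorescence list for inflorescence against apex t2 (0.0653, against 0.0309). It changed no other call of a named gene or of a list at either correlation.

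Changed genes are given in the order apex t0 against leaf, inflorescence against apex t2 and inflorescence against leaf. With only genes marked in all 8 libraries, H3K4me3 gave 574, 1 and 70, and H3K27me3 127, 5 and 20. With genes without an island set to the lowest island density, the counts were 832, 28 and 139 for H3K4me3 and 396, 56 and 64 for H3K27me3. Merged island regions present in all 8 libraries gave 663, 1 and 101 changed regions, not genes, for H3K4me3 and 364, 39 and 71 for H3K27me3. For inflorescence against apex t2 with no filter, 53 H3K4me3 and 112 H3K27me3 genes changed, and for H3K4me3 it was 107 with 300 bp on either side, 105 with control reads subtracted and 133 with a pseudocount of 5. With islands of a fold of at least 2, 22 H3K27me3 genes changed for apex t2 against apex t0.

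Signs of 9 results turned when genes without an island were set to the lowest island density over the whole gene body. Marked libraries count reads inside islands only, so these turns partly follow unequal lengths and do not decide against the calls. For H3K4me3 these were LAP6 for inflorescence against apex t2 (0.34) and, for inflorescence against leaf, KNAT2 (-0.99), KNAT6 (-0.64), KNAT1 (-0.19), AIL6 (-0.94), STM (-0.72), SEP1 (-0.18) and AP3 (-0.10). For H3K27me3 it was ANT for inflorescence against apex t2 (-0.33).

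Genes that gained or lost H3K4me3 islands for apex t2 against apex t0 numbered 168 with at least 0.5 of the body covered and 138 with a fold of at least 2. With an estimated correlation, 0 H3K4me3 lists passed in any of the 4 comparisons, and for H3K27me3 it was 0 for apex t0 against leaf, 1 for inflorescence against apex t2 and 0 for inflorescence against leaf. Genes with both marks numbered 282 in leaf, 569 in apex t0, 523 in apex t2 and 392 in the inflorescence with 0.5 of the body covered, and 1046, 903 and 594 in the last 3 with a fold of at least 2. With only genes marked in all 16 libraries, opposite changes numbered 9, 0 and 2 for apex t0 against leaf, inflorescence against apex t2 and inflorescence against leaf.

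Leaving out 1 library at a time leaves 1 sample in a stage, which is assumed to vary like the others. Changed H3K4me3 genes ran from 659 to 3135 (apex t0 against leaf), 0 to 0 (apex t2 against apex t0), 0 to 2 (inflorescence against apex t2) and 68 to 1835 (inflorescence against leaf). In the same order, H3K27me3 ran from 636 to 1698, 0 to 11, 0 to 980 and 387 to 1286. Gained or lost islands ran from 1381 to 2253, 193 to 430, 712 to 1255 and 829 to 1498 for H3K4me3, and from 1323 to 2557, 166 to 288, 597 to 1592 and 838 to 1454 for H3K27me3. Lists past the threshold ran from 3 to 5, 2 to 4, 2 to 5 and 2 to 5 for H3K4me3, and from 1 to 3, 0 to 2, 1 to 3 and 1 to 3 for H3K27me3. Genes with both marks ran from 984 to 1699 in leaf, 1675 to 2182 in apex t0, 1683 to 1958 in apex t2 and 1336 to 1691 in the inflorescence. Counts of gained or lost islands and of both marks can only stay or rise here, since a library left out drops a condition. Opposite changes ran from 84 to 223, 0 to 0, 0 to 19 and 7 to 85. The extremes without leaf replicate 2 were 3135 and 1835 for H3K4me3 and 1698 and 1286 for H3K27me3, and the 980 was without inflorescence replicate 2.

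Depth limits presence and absence of islands, since replicate 1 held 3779918 to 14763262 island reads and replicate 2 13745836 to 23673881.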

Other observations

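The tests of tissue composition in the inflorescence and both tests on the missing calls for apex t2 against apex t0 were chosen only after the results were seen.

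KNAT6, LFY, SOC1, BLH9 and ANT had less H3K27me3 in apex t0 than in leaf and more of it in the inflorescence than at apex t2. Across genes the inflorescence minus apex t2 changes correlated with those of apex t0 minus leaf by r = -0.534 for 17631 H3K4me3 genes and -0.622 for 8678 H3K27me3 genes, but the apex enters both contrasts with opposite sign and its 2 stages were near alike (r = 0.942 and 0.952 between their mean levels), so a negative r arises without any return. For the same reason the r among genes with the same covered length in all 8 libraries, -0.358 (1420 genes) and -0.458 (2465 genes), does not decide whether the control that leaf and inflorescence shared could be the source. Genes called for apex t0 against leaf and marked in all 8 libraries had a median return of 0.273 (95% interval 0.233 to 0.305, 591 of 706 genes towards leaf) for H3K4me3. For H3K27me3 it was 0.365 (0.308 to 0.403, 183 of 214 genes). A return above 0 was favoured in advance, since the near alike apex stages enter both contrasts and the genes were selected for their difference from leaf. Neither the medians nor the counts towards leaf therefore show a return. The intervals resampled genes, which are not independent replicates. The bound of 0.8 set for genotype as the whole cause was wrong, since genotype on top of tissue differences gives a partial return, and genotype stays open. Fewer meristem cells and more green tissue in the inflorescence may contribute and stay open too, as the larger adjusted p of the 2 lists in H3K4me3 with an estimated correlation was 0.154, so shared control, genotype and tissue cannot be told apart.

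Genes that gained H3K27me3 in apex t0 against leaf lay next to each other, in 85 neighbouring pairs among 724 genes. The 1000 shuffles over 18168 eligible genes gave at most 37. An island over neighbouring genes makes a pair by itself, which shuffles of single genes do not allow for. The excess thus shows only that the gained genes were not scattered one by one. The shuffles placed genes singly, so they do not show that both genes of a pair gained the mark independently. A single island spanned both genes in both apex t0 libraries in 50.6% of the pairs (43 pairs), and 42 pairs were not spanned. Islands over gene pairs may account for part of the pattern, and this stays open, because the share lay between the bounds set for either outcome.

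No gene passed for apex t2 against apex t0, although AP3 gained H3K4me3 islands, of low fold, in both replicates. The fit recovered at least 75.8% of simulated 4-fold changes in each mark, just short of the bound of 80 set for excluding too few libraries, so low power could still hide changes, above all smaller ones. The simulation used the 14688 and 5914 genes marked in all 8 libraries, and recovery for genes that gain or lose islands, such as AP3, was not simulated. A shift between replicate batches that is common to the stages was argued against as the whole cause: the replicate block, which raised the calls for apex t0 against leaf from 1418 to 2382 for H3K4me3 and from 833 to 889 for H3K27me3 and lowered those for inflorescence against apex t2 from 226 to 156 for H3K4me3, called 0 genes here for either mark. Replicates agreed less in leaf and inflorescence than in the apices. For H3K27me3 the Spearman correlation of gene reads between replicates was 0.806 and 0.803, against 0.95 (t0) and 0.947 (t2). For H3K4me3 it was 0.801 and 0.851, against 0.883 and 0.945. The fits with and without the block both pool the spread of all stages into this comparison. Whether that hid changes was not tested.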
